A study of Arabidopsis thaliana with 8 samples.

How the data were processed

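RNA from shoots of 4-day-old Arabidopsis thaliana seedlings was hybridised to 8 one-colour Agilent arrays, one per sample. There were 3 samples of MP-Dof5.8 line 3, 3 of MP-GUS line 1, and 1 each of MP-Dof5.8 line 4 and MP-GUS line 4. Per the labels' protocols, seed was stratified for 4 days, the MP:Dof5.8 lines were hemizygous and the MP:GUS lines homozygous, and RNA was extracted with TRIzol, treated with DNase and cleaned on RNeasy columns. The authors labelled 1000 ng of RNA with Cy3 by the One-Color Quick Amp kit. The deposited scanner files hold an intensity per spot, made with Agilent Feature Extraction 9.1 per the submitters' processing notes (9.1.3.1 per the file headers). Per the file headers the processed intensity is background-subtracted and detrended within the array, with dim spots replaced by a surrogate value, and is not scaled between arrays. The mean spot intensity and the median local background intensity of the same deposited files are unprocessed. The deposited table of values holds a linear ratio: each column is the processed intensity divided by the array's 75th percentile over all spots, as read from the values, with column medians from 0.1353 to 0.1433. The tool used for that scaling is not given in the sources used here.

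Each array held 45220 spots, 1417 of them controls. Of the 43803 probe spots, 29866 to 31474 per array were well above background, 7 to 73 were marked as non-uniform and 0 were saturated, and 6328 to 9329 spots held a surrogate value. The 75th percentile of the signal lay between 1851 and 2152. The lowest level of a spot well above background lay between -7.43 and -6.43 on the log2 scale used here.

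Processed intensities were taken to log2 and the array's 75th percentile over non-control probes was subtracted. Spots marked as non-uniform were left out and spots of the same probe were averaged. Probes well above background on at least 3 of the 8 arrays were kept, 30951 of 43603. A gene, by its locus in the array annotation, was read by its kept probe with the highest mean, and 161 probes with a locus were dropped for a non-uniform spot. This gave 20480 genes, 6082 of them with several probes, of which 1155 had probes whose differences did not have the same sign. Of the 2431 kept probes without a locus, 2421 were tested apart and the others were dropped for a non-uniform spot. Gene symbols and neighbouring genes came from a RefSeq gene table of assembly TAIR10.1, which held 20280 of the tested genes and was used for nothing else.

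Linear models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with version 1.17.8 of data.table for reading, and a Benjamini-Hochberg adjusted p under 0.05 counted as a change. All lines were compared as 4 MP:Dof5.8 against 4 MP:GUS arrays. A fit with a mean per line gave line 3 against line 1, line 4 against line 4, the difference between these, and MP-GUS line 4 against line 1. In that fit the lines with 1 array are assumed to vary like those with 3. The agreement of the pairs of lines is the share of genes called in line 3 that have the same sign in line 4. Its 95% interval is the exact binomial interval. DOF5.8 was also tested by exact permutation over the 70 assignments of 4 and 4 arrays. Where a gene was well above background on no array of a group, its fold is given as a lower bound: the mean of the brighter group minus the mean of the dimmer one, with each dim value raised to the lowest level well above background on its array. No such bound is given where neither group was well above background. A p-value beside a bound comes from the fit of the values as measured, dim ones included, and does not test the bound.

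The 20 gene lists were the Dof family; auxin response; auxin transport and synthesis; MONOPTEROS and its reported targets; procambium, xylem and phloem; cytokinin response and metabolism; gibberellin and brassinosteroid; shoot meristem and leaf development; photosynthesis; heat shock; salicylic acid and defence; jasmonate; glucosinolate; flavonoid and anthocyanin; clock and flowering; cell cycle; nitrogen assimilation; root tissue markers; seed storage markers; and stomatal lineage and epidermis markers. They were written from general knowledge of the genes and hold 379 genes, 340 of them measured, and the reference table gives the listed symbol at that locus for 355. Each was tested with camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 20 lists. DOF5.8 itself was not counted in the Dof family.

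The comparisons, the tests, the gene-naming rule and most alternatives were chosen before the data were examined. The rule names DOF5.8 and MP; over all lines the 10 genes with the largest differences in each direction among those called with no overlap between the groups, and the 5 largest in each direction that have a symbol; for line 3 the 5 largest in each direction; for the difference and the control lines the 3 largest in each direction; and of each list up to 4 measured members with the smallest adjusted p.

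The alternatives were normexp background correction with an offset of 50; quantile normalization; the array median in place of the 75th percentile; the deposited value table; no filter on dim probes, or well above background on all 8 arrays; the mean of a gene's probes; an intensity trend in the variance; slide as a block; label numbers or pairs of lines as blocks; line means; a 2-fold threshold; and leaving out each array. Chosen after seeing the data were fits within each slide and normexp with the local background capped at 2 times the array's median. The closing part gives their effect.

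The procedure was tested on simulated data with 20480 genes, 200 of them changed. Over all lines it recovered 74.6%, 95.5% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, with 7 false calls, and with slide as a block 62.7%, 95.5% and 97% with 3 false calls. For the same sizes it recovered 56.7%, 92.5% and 98.5% in line 3 against line 1 (10 false calls), 7.46%, 52.2% and 92.4% in line 4 against line 4 (2), 1.49%, 55.2% and 81.8% for the difference between the pairs (4) and 28.4%, 83.6% and 93.9% for the control lines (10). Of 20 simulated lists, the 1 shifted by 0.5 was called and 0 others were. The simulated genes varied independently, without slide effects or other line effects. These numbers therefore do not cover errors from slide, line or correlation between genes.

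The sequence context of the probes was not analysed here, and control spots were not used here beyond the background fit of normexp.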

Results

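The series measured gene expression in shoots of 4-day-old Arabidopsis thaliana seedlings on 8 one-colour Agilent arrays, one array per sample. The question was what changes in the shoot when DOF5.8, which encodes a Dof-type zinc-finger transcription factor, is expressed from the promoter of MONOPTEROS (MP). MP encodes an auxin response factor needed for vascular and embryo patterning. The comparison plants expressed the reporter enzyme GUS from the same promoter. Of the 4 MP:Dof5.8 samples, 3 came from line 3 and 1 from line 4, and of the 4 MP:GUS samples, 3 came from line 1 and 1 from line 4. The seedlings were selected on 10 µg/ml glufosinate ammonium and grown under continuous light at 23 °C. The MP:Dof5.8 lines were hemizygous and the MP:GUS lines homozygous. Zygosity thus coincided with construct, and these data cannot tell the effects of the 2 apart. Between 68.2% and 71.9% of the 43803 probe spots per array were well above background, no spot was saturated, and 20480 genes were tested. Signals correlated between arrays of the same line with r from 0.987 to 0.994 and between arrays of different lines with r from 0.965 to 0.992, across genes. All levels below are log2 signals relative to the array's 75th percentile. The number of arrays limits the precision, and the labels do not say that the samples of a line were separate cultures, so p-values measure only the spread between these samples. The 3 arrays of a line are not separate lines, and the tests of 4 against 4 arrays count arrays rather than lines. The arrays lay on 2 slides: slide 1 held the 3 arrays of MP-Dof5.8 line 3 and 1 array of MP-GUS line 1, and slide 2 held the other two arrays of MP-GUS line 1 and both lines 4.

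DOF5.8 (AT5G66940) itself was higher in every MP:Dof5.8 sample than in any MP:GUS sample. Its level was 2.23 ± 0.05 in MP:Dof5.8 and -2.37 ± 0.14 in MP:GUS (SD, n = 4 each), a difference of 4.61 on the log2 scale or 24.4-fold (limma adjusted p = 2.1e-07). An exact two-sided permutation test gave p = 0.0286, the smallest that 4 against 4 arrays allow. It exchanges arrays, although 3 of the 4 arrays of each construct came from the same line. The difference was 4.52 between MP-Dof5.8 line 3 and MP-GUS line 1 and 4.87 between the lines 4, 4.58 with slide as a block, and 4.46 and 4.71 within slides 1 and 2. One probe of 60 bases read the gene, and its place on the transcript was not analysed here. MP (AT1G19850), whose promoter drove both constructs, stood at 0.36 ± 0.10 in MP:Dof5.8 and 0.53 ± 0.12 in MP:GUS (SD, n = 4 each), a difference of -0.18 that did not pass the test (adjusted p = 0.174, and 0.111 with slide as a block).

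**Figure D1:**
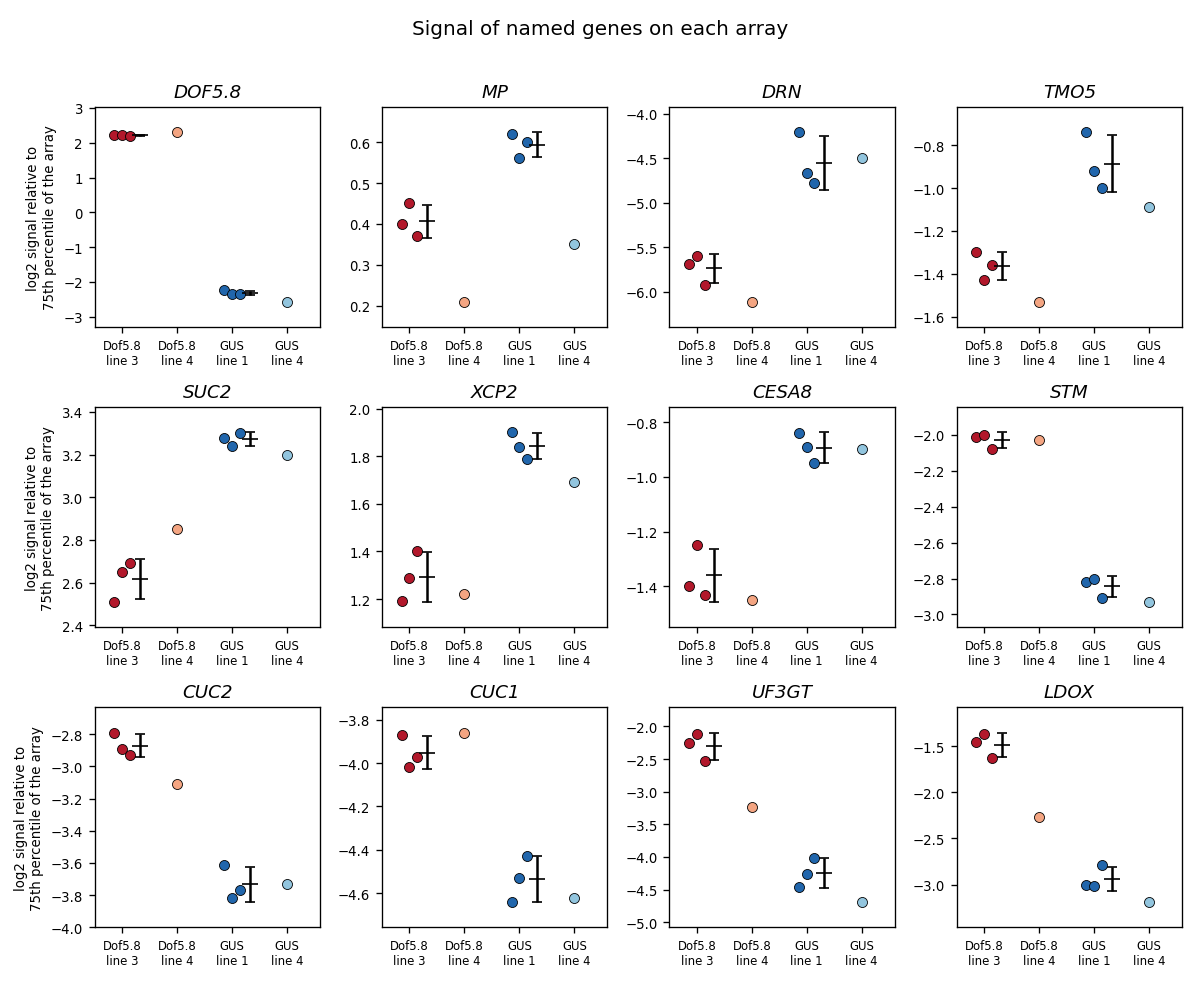
Log2 signal relative to the array's 75th percentile (vertical axis) of 12 genes on each of the 8 arrays, by line; each point is an array, and the bars are the mean ± SD of lines with 3 arrays. DOF5.8 lay between 2.19 and 2.30 on the MP:Dof5.8 arrays and between -2.57 and -2.24 on the MP:GUS arrays.

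The question put to all lines together was which genes differ between the 4 MP:Dof5.8 and the 4 MP:GUS arrays. Of genes of the shoot meristem and leaf development 5 of 22 rose, of flavonoid and anthocyanin genes 6 of 15 rose, and of genes of procambium, xylem and phloem 9 of 31 fell and 3 rose. Camera called each of these lists, with adjusted p = 0.42 for each with an estimated correlation. The steepest differences downwards were in genes that stood well above background on all 4 MP:GUS arrays and on none of the MP:Dof5.8 arrays, so only a lower bound of the fold can be given. Here and below, the p-values beside bounds belong to the fitted differences, which include dim values, and not to the bounds. AT1G52070, a jacalin-type lectin, was at least 31.6-fold lower (limma adjusted p = 5.36e-05), and the cysteine peptidase CEP2 (AT3G48340) at least 20.1-fold lower (adjusted p = 9.76e-05). The peroxidase AT4G30170 was at least 30.4-fold lower (adjusted p = 0.000543), and the late-embryogenesis-abundant-related genes AT5G54370 and AT5G60530 were at least 19.3-fold and 17.7-fold lower. The arabinogalactan protein gene AGP30 (AT2G33790) was at least 15.7-fold lower, AT5G04120, of the phosphoglycerate mutase family, at least 12.9-fold, the beta-glucosidase BGLU35 (AT1G51470) at least 10.5-fold and the sulfotransferase ST4B (AT1G13420) at least 8.23-fold, with adjusted p-values from 8.01e-05 to 0.0036. The beta-glucosidase BGLU21 (AT1G66270) and the transposable element gene AT5G35935 were each well above background on 1 of the 4 MP:Dof5.8 arrays and fell by 5.36 and 5.27 on the log2 scale (adjusted p = 0.00787 and 0.00898). All of these genes stayed called with slide as a block, with adjusted p-values from 0.000494 to 0.0297. With capped normexp, whose offset shrinks the differences of dim genes, AT5G04120 lost its call (adjusted p = 0.0511). The root tissue markers moved with them: of 13 measured, 4 were lower and 0 higher (1 higher and 6 lower adjusted over the list alone).

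The root tissue markers had a median log2 difference of -0.71, or -0.57 with bounded genes at their bound (camera adjusted p = 0.0023, and adjusted p = 0.42 with an estimated correlation). The mean of the root tissue markers was -1.14, and it was -0.33 with capped normexp (adjusted p = 0.0061) and -0.42 with only probes well above background on all 8 arrays, where the call was lost (adjusted p = 0.22). The median was -0.81 with slide as a block (camera adjusted p = 0.003, and adjusted p = 0.25 with an estimated correlation), and it was -0.54 and -0.78 within slides 1 and 2. The root hair expansins EXPA7 and EXPA18 were at least 3.38-fold and 1.47-fold lower (adjusted p = 0.00948 and 0.00787) and the root hair wall protein gene PRP3 at least 1.57-fold lower (adjusted p = 0.0123), none of them well above background on any MP:Dof5.8 array. EXPA18 and PRP3 were well above background on 3 of the 4 MP:GUS arrays. WOX5, which marks the quiescent centre of the root tip, fell by 0.93 (SE 0.21, adjusted p = 0.037). That call was lost without any single array other than MP-Dof5.8 line 3 replicate 2 or MP-Dof5.8 line 4, with an adjusted p of up to 0.0993. The root endodermis genes CASP1, CASP2 and MYB36, named after their values were seen, stood at -0.41, -0.16 and 0.15 (adjusted p = 0.171, 0.433 and 0.497). The call of PRP3 was lost with capped normexp (adjusted p = 0.0642) and that of WOX5 with no filter on dim probes (0.0642).

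Among the genes that rose, MRD1 (AT1G53480) differed by 6.42 on the log2 scale (SE 0.18), from -5.13 ± 0.34 in MP:GUS to 1.29 ± 0.22 in MP:Dof5.8 (SD, n = 4 each; adjusted p = 5.57e-06). AT5G03090, which the array annotation describes as similar to MRD1, rose by 2.2 (SE 0.14, adjusted p = 0.000231), and the glutamate dehydrogenase gene GDH3 (AT3G03910) by 2.32 (SE 0.18, adjusted p = 0.000539). PCC1 (AT3G22231), a gene controlled by pathogens and the clock, rose by 1.87 (adjusted p = 0.0112), measured above background on 2 of the 4 MP:GUS arrays. The ethylene-response-factor gene ESE2 (AT2G25820) rose by 1.87 (adjusted p = 0.0159), measured on 3 of them. The carboxypeptidase SCPL32 (AT1G61130) was at least 1.91-fold higher (adjusted p = 0.0119), AT1G07175 at least 1.42-fold (adjusted p = 0.0328) and the B3-domain gene REM1 (AT4G31610) at least 1.23-fold (adjusted p = 0.0172), none of them well above background in MP:GUS. REM1 was well above background on 3 of the 4 MP:Dof5.8 arrays. AT4G26950, of unknown function, rose by 1.96 (adjusted p = 0.0273). With slide as a block the adjusted p rose to 0.101 for AT1G07175, 0.0881 for AT4G26950 and 0.0551 for ESE2, and the others stayed called. Leaving out 1 array ended the call of ESE2 without MP-Dof5.8 line 3 replicate 2 or MP-GUS line 1 replicate 3 (adjusted p up to 0.0547). It ended those of AT1G07175 (up to 0.0876), AT4G26950 (up to 0.0866) and REM1 (up to 0.0589) for most arrays: all but MP-Dof5.8 line 3 replicate 1 and MP-Dof5.8 line 4 for AT1G07175, those and MP-Dof5.8 line 3 replicate 3 for AT4G26950, and all but MP-GUS line 1 replicates 1 and 3 and MP-Dof5.8 line 4 for REM1. With capped normexp SCPL32, AT1G07175, AT4G26950 and REM1 lost their calls (adjusted p = 0.206, 0.158, 0.0767 and 0.0578), and so did AT1G07175 with no filter on dim probes (0.0568).

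Of the 11 measured genes in the list of MP and its reported targets, 3 fell and 2 rose, the same numbers as adjusted over the list alone. DRN (AT1G12980), an AP2-type regulator of embryo and shoot patterning, fell by 1.29 (SE 0.15, adjusted p = 0.00295), and the bHLH gene TMO5 (AT3G25710) by 0.47 (SE 0.09, adjusted p = 0.0193). The bHLH gene TMO7 (AT1G74500) was not well above background on any MP:Dof5.8 array and well above it on 3 of the 4 MP:GUS arrays, at least 1.66-fold lower in MP:Dof5.8 (adjusted p = 0.00288). IAA12, whose product represses MP, rose by 0.33 (SE 0.06, adjusted p = 0.0174), and ANT, an AP2 gene of organ growth named after its value was seen, by 0.36 (adjusted p = 0.0467, and 0.102 with slide as a block). The list did not shift as a whole (median -0.13, camera adjusted p = 0.25). It did with slide as a block, downwards, with a median of -0.14 (adjusted p = 0.034, and adjusted p = 0.34 with an estimated correlation), and within slides 1 and 2 the medians were -0.15 and -0.19. TMO5 lost its call without MP-Dof5.8 line 3 replicate 2 or 3 or MP-GUS line 1 replicate 2 (adjusted p up to 0.0667), and IAA12 without MP-Dof5.8 line 3 replicate 2 or MP-GUS line 1 replicate 2 or 3 (up to 0.0656). Both lost it with capped normexp (adjusted p = 0.104 and 0.0516).

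Genes of procambium, xylem and phloem fell more often than they rose: 9 of 31 measured were lower and 3 higher (12 lower and 3 higher adjusted over the list alone). CESA8, CESA7 and CESA4, subunits of the cellulose synthase of secondary walls, fell by 0.49 (SE 0.06, adjusted p = 0.00292), 0.36 (SE 0.05, adjusted p = 0.00381) and 0.33 (adjusted p = 0.0405). XCP2, a peptidase of maturing xylem vessels, fell by 0.53 (SE 0.07, adjusted p = 0.00405), and SUC2, the sucrose transporter of phloem companion cells, by 0.58 (SE 0.07, adjusted p = 0.00374). The 3 higher members, named after their values were seen, were the HD-ZIP gene ATHB15 (0.30), LHW, which encodes a partner of TMO5 (0.40), and the phloem gene OPS (0.60). LHW and OPS had adjusted p-values of 0.1 and 0.0586 with slide as a block. The list had a median of -0.24 (camera adjusted p = 0.0023, and adjusted p = 0.42 with an estimated correlation), -0.22 with slide as a block (adjusted p = 5.7e-05, and 0.16 with an estimated correlation), and -0.26 and -0.19 within slides 1 and 2. The root tissue markers moved in the same direction on both slides, with medians of -0.54 and -0.78.

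Of genes of the shoot meristem and of leaf development 5 of 22 measured were higher and 0 lower (8 higher and 1 lower adjusted over the list alone). STM (AT1G62360), the homeobox gene that maintains the shoot meristem, rose by 0.83 (SE 0.05, adjusted p = 0.000178). CUC2 (AT5G53950) and CUC1 (AT3G15170), NAC genes of organ boundaries, rose by 0.80 (SE 0.08, adjusted p = 0.00148) and 0.63 (SE 0.07, adjusted p = 0.00167). The KNOX homeobox gene BP rose by 0.56 (SE 0.11, adjusted p = 0.0217), and KNAT2, of the same family and named after its value was seen, by 0.55 (adjusted p = 0.03). All 5 stayed called with slide as a block. The list's median was 0.18 (camera adjusted p = 0.014, and adjusted p = 0.42 with an estimated correlation), 0.18 with slide as a block (adjusted p = 0.003, and 0.16 with an estimated correlation), and 0.21 and 0.22 within slides 1 and 2. Without MP-Dof5.8 line 4 the list's call was lost (adjusted p = 0.072), and that of BP was lost without any single array other than MP-GUS line 1 replicate 1 or MP-Dof5.8 line 4 (up to 0.072). With normexp background correction, where the background fit failed on 1 array, CUC2 (all lines) and CUC1 (all lines) read -0.11 and -0.38.

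Of genes of flavonoid and anthocyanin synthesis 6 of 15 measured were higher and 0 lower (8 higher and 0 lower adjusted over the list alone). The reductase gene DFR rose by 1.23 (SE 0.14, adjusted p = 0.0021) and the dioxygenase gene LDOX by 1.32 (SE 0.20, adjusted p = 0.00768). The anthocyanin-decorating enzymes UF3GT and 5MAT rose by 1.82 (SE 0.26, adjusted p = 0.00615) and 1.62 (SE 0.23, adjusted p = 0.0064). The list's median was 0.67 (camera adjusted p = 4.2e-05, and adjusted p = 0.42 with an estimated correlation), 0.47 with slide as a block (adjusted p = 5.7e-05, and 0.34 with an estimated correlation), and 0.69 and 0.24 within slides 1 and 2. The glucosinolate genes had a median of 0.57 (camera adjusted p = 0.00083, and adjusted p = 0.64 with an estimated correlation), but none of the 20 passed the test singly, also when adjusted over the list alone. The transcription factor gene MYB28 and the enzyme genes BCAT4, CYP83A1 and MAM1 stood at 1.16, 0.57, 0.58 and 0.32 (adjusted p from 0.0749 to 0.0887). Their shift was 0.25 with slide as a block (camera adjusted p = 0.033, and 0.73 with an estimated correlation). The medians were 0.59 within slide 1 and -0.06 within slide 2, where 1 MP:Dof5.8 array stands mostly against MP-GUS line 1, and 0.41 between the lines 4 on that slide.

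Auxin genes moved both ways. Of 30 measured auxin response genes, 4 were higher and 6 lower (6 and 9 adjusted over the list alone). The auxin-conjugating enzymes GH3.3 and GH3.2 fell by 0.75 (SE 0.07, adjusted p = 0.0011) and 0.83 (SE 0.14, adjusted p = 0.0118), and the Aux/IAA gene IAA30 by 0.82 (SE 0.10, adjusted p = 0.00365), while SAUR19, of a family linked to cell expansion, rose by 0.95 (SE 0.11, adjusted p = 0.00238). The other 3 higher genes, IAA12, SAUR63 and IAA20, were 0.33, 0.70 and 0.46 higher, the last with an adjusted p of 0.13 with slide as a block. The auxin response list had a median of -0.23 (camera adjusted p = 0.11, and 0.021 without MP-Dof5.8 line 4), -0.07 with slide as a block, and -0.21 and 0.07 within slides 1 and 2. Of 18 genes of auxin transport and synthesis, 1 was higher and 2 lower (2 and 3 adjusted over the list alone; median 0.05, camera adjusted p = 0.78). The influx carrier gene LAX2 fell by 0.41 (adjusted p = 0.00749) and the biosynthesis gene YUC1 by 0.66 (adjusted p = 0.0121), and the kinase gene PID rose by 0.48 (adjusted p = 0.0207). LAX3 differed by 0.22 (adjusted p = 0.0694). The call of PID was lost without any of the MP-Dof5.8 line 3 arrays or MP-GUS line 1 replicate 2 or 3 (adjusted p up to 0.0683).

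Of 21 cytokinin genes, 2 were higher and 2 lower (2 and 3 adjusted over the list alone). The cytokinin-activating enzyme gene LOG3 rose by 0.89 (SE 0.14, adjusted p = 0.00844) and its homologue LOG7 fell by 0.98 (SE 0.24, adjusted p = 0.0485). The cytokinin oxidase gene CKX5 rose by 0.77 (SE 0.13, adjusted p = 0.0139), and the response regulator ARR3, well above background on 3 of the 4 MP:GUS arrays and on no MP:Dof5.8 array, was at least 1.27-fold lower (adjusted p = 0.00868). The cytokinin list's median was -0.10 and its mean -0.03 while the test pointed up (camera adjusted p = 0.85). The call of LOG7 was lost with slide as a block (adjusted p = 0.135) and without any single array other than MP-Dof5.8 line 4 (up to 0.139). With normexp background correction, LOG3 (all lines) and CKX5 (all lines) read -0.04 and -0.02. ARR3 lost its call with capped normexp (adjusted p = 0.0766) and LOG7 with no filter on dim probes (0.0833). Of 14 gibberellin and brassinosteroid genes, 0 were higher and 2 lower (1 and 4 adjusted over the list alone; median -0.45, camera adjusted p = 0.29). The brassinosteroid synthesis genes BR6OX2 and CPD fell by 0.47 (adjusted p = 0.0267) and 0.52 (adjusted p = 0.0338), while DWF4 and GA20OX2 stood at -0.70 and -0.99 (adjusted p = 0.0558 and 0.0535). BR6OX2 and CPD had adjusted p-values of 0.0555 and 0.0875 with slide as a block. Both calls were lost without any single array other than MP-Dof5.8 line 4 and, for BR6OX2, MP-GUS line 1 replicate 1 (up to 0.0808 and 0.105), and with no filter on dim probes (0.0515 and 0.0618). CPD was also not called with quantile normalization (0.0512) or capped normexp (0.0501).

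Of 16 nitrogen assimilation genes 4 fell and 0 rose (5 and 0 adjusted over the list alone). The nitrate reductases NIA2 and NIA1 fell by 0.51 (SE 0.06, adjusted p = 0.00352) and 0.61 (SE 0.10, adjusted p = 0.0137), the nitrite reductase NIR1 by 0.33 (SE 0.07, adjusted p = 0.0355) and the glutamine synthetase GLN1;4 by 0.54 (SE 0.07, adjusted p = 0.00554). Their list had a median of -0.12 (camera adjusted p = 0.15, and 0.038 with slide as a block, where adjusted p = 0.25 with an estimated correlation). FT, the mobile flowering signal, fell by 1.31 (SE 0.13, adjusted p = 0.00149), the 1 of 16 clock and flowering genes that passed, also over the list alone. PRR7, LUX and GI stood at -0.38, -0.14 and -0.18 (adjusted p from 0.0702 to 0.142), and that list's median was -0.10 (camera adjusted p = 0.15, and 0.025 with slide as a block, where adjusted p = 0.25 with an estimated correlation). PR5, a marker of salicylic acid response, fell by 0.83 (SE 0.06, adjusted p = 0.00045), the 1 of 11 defence genes that passed, also over the list alone. PAD3, SARD1 and NIMIN1 stood at -0.39, 0.78 and 0.61 (adjusted p from 0.0812 to 0.172), and the defence list's median was 0.07 and its mean 0.08 while the test pointed down (camera adjusted p = 0.78). Of 11 jasmonate genes none passed over all genes and 2 were lower adjusted over the list alone (median -0.01, camera adjusted p = 0.93). JAZ2, JAZ10, LOX2 and AOS stood at -0.35, -0.50, 0.44 and 0.30 (adjusted p from 0.0542 to 0.122). NIR1 lost its call without MP-Dof5.8 line 3 replicate 2 or 3 or any MP-GUS line 1 array (adjusted p up to 0.1), with capped normexp (0.187), with no filter on dim probes (0.0703) and with quantile normalization (0.0506).

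The photosynthesis list had a median of -0.10 (camera adjusted p = 0.0054, and adjusted p = 0.67 with an estimated correlation), pointed up relative to all genes with normexp background correction (mean -0.03, adjusted p = 0.65) and was not called with quantile normalization (adjusted p = 0.54) or without MP-GUS line 1 replicate 3 (adjusted p = 0.083). Of its 30 genes 2 fell and 0 rose, also over the list alone, and 27 of the 30 were above 0 between the lines 4. The antenna protein genes LHCB2.1 and LHCB4.2 fell by 0.73 (adjusted p = 0.0124) and 0.39 (adjusted p = 0.0284), LHCB4.2 not with slide as a block (adjusted p = 0.0699) nor without any single array other than MP-Dof5.8 line 4 (up to 0.0942), with quantile normalization (0.0967) or with no filter on dim probes (0.0565). LHCB2.1 was not called as the mean of its probes (adjusted p = 0.105). LHCA4 stood at -0.24 (0.05 between the lines 4) and LHCB3 at -0.26 (adjusted p = 0.0914 and 0.111). The photosynthesis median was -0.07 with slide as a block (camera adjusted p = 0.033, and 0.73 with an estimated correlation), and -0.05 and -0.09 within slides 1 and 2. Of 18 cell cycle genes 1 was higher and 0 lower (2 and 0 over the list alone), with a median of 0.17 (camera adjusted p = 0.00083, and adjusted p = 0.54 with an estimated correlation). That median was 0.08 with slide as a block (adjusted p = 0.011, and 0.58 with an estimated correlation), and 0.17 and 0.04 within slides 1 and 2. The mitotic cyclin gene CYCA1;1 rose by 0.27 (adjusted p = 0.0405, and 0.0909 with slide as a block), a call lost without any single array other than MP-Dof5.8 line 4 (up to 0.124) and with no filter on dim probes (0.0825). KRP2, CYCB1;1 and KRP1 stood at 0.49, 0.30 and 0.41 (adjusted p from 0.0556 to 0.093).

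Of 5 measured heat shock genes 1 was higher and 0 lower, also over the list alone: the small heat shock protein gene HSP18.2 rose by 0.57 (SE 0.07, adjusted p = 0.00352). HSP90.1, HSFA2 and HSP101 stood at 0.79, 2.04 and 0.76 (adjusted p from 0.158 to 0.173). The list had a median of 0.79 (camera adjusted p = 0.014, and adjusted p = 0.54 with an estimated correlation), 0.36 with slide as a block (adjusted p = 0.041, and 0.58 with an estimated correlation), and 0.69 and 0.02 within slides 1 and 2 (0.56 between the lines 4). Of 13 stomatal lineage and epidermis markers 1 was higher and 0 lower (2 and 0 over the list alone): the epidermal regulator GL2 rose by 0.43 (SE 0.06, adjusted p = 0.00391). GL3, EPF2 and MUTE stood at 0.63, 0.31 (-0.03 between the lines 4) and 0.25 (adjusted p from 0.0608 to 0.14). The median was 0.12 (camera adjusted p = 0.036, and adjusted p = 0.54 with an estimated correlation), 0.05 with slide as a block (adjusted p = 0.22), and 0.11 and 0.03 within slides 1 and 2. That call was also lost without MP-Dof5.8 line 3 replicate 1 or 2 or MP-GUS line 1 replicate 3 (adjusted p of 0.096, 0.068 and 0.071) and with quantile normalization (0.055). Of 26 other Dof genes 1 was higher and 1 lower (1 and 4 over the list alone; median -0.09, camera adjusted p = 0.13). DOF1.6 fell by 0.42 (SE 0.06, adjusted p = 0.00533) and DOF5.7 stood at -0.17 (adjusted p = 0.0534). DOF3.4 rose by 0.49 (SE 0.09, adjusted p = 0.0174), but not without MP-Dof5.8 line 3 replicate 3 or MP-GUS line 1 replicate 3 (adjusted p up to 0.0583) or with slide as a block (0.0563), and DOF3.4 (all lines) read -0.11 as the mean of its probes. None of 4 seed storage markers passed, also over the list alone (median -0.64, camera adjusted p = 0.75). CRA1, OLEO1 and OLEO2 stood at -1.71, -0.65 and -0.62 (2.38, 1.87 and 1.85 between the lines 4) and EM6 at 0.34.

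**Figure D2:**
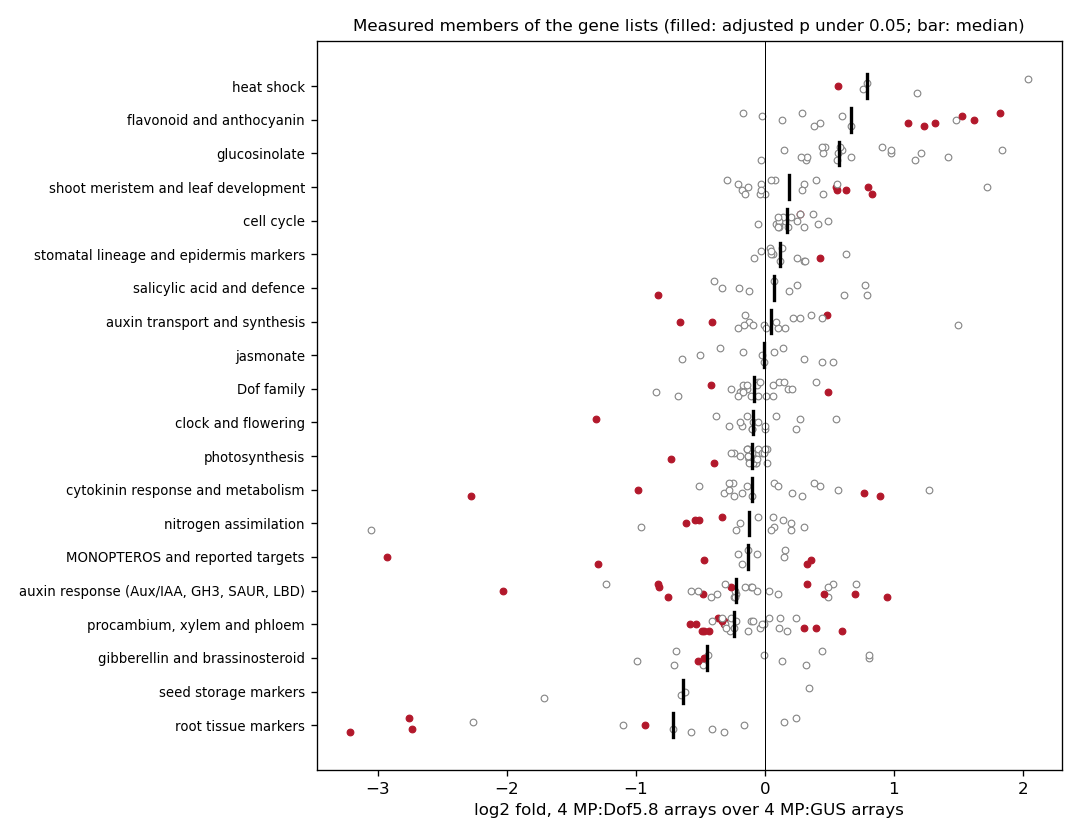
Fitted log2 difference, MP:Dof5.8 minus MP:GUS over 4 and 4 arrays (horizontal axis), of each measured member of the 20 gene lists; filled points had an adjusted p under 0.05 and bars are medians. The median lay at 0.67 for flavonoid genes, 0.18 for shoot meristem genes, -0.24 for vascular genes and -0.71 for root tissue markers; points of genes not well above background in a group are fitted values only.

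Over all genes, 1726 of 20480 (8.43%) were called with limma, 782 higher and 944 lower, and 6479 had an unadjusted p under 0.05. At least 2-fold changes were called for 67 genes upwards and 282 downwards. The same fit with the arrays split by slide in place of construct called 4840 genes. With slide as a block 1074 genes were called (407 higher, 667 lower), of which 929 were among the 1726. Within slide 1 alone 27 genes were called and within slide 2 alone 9, with 5455 and 2133 at an unadjusted p under 0.05. Each of these tests has 1 array on one side (1 of MP-GUS line 1 on slide 1, and 1 of MP-Dof5.8 line 4 on slide 2), assumed to vary like the others, and the MP:Dof5.8 lines differ between them. Of the 20 lists, 9 were called by camera and 0 with an estimated correlation (2 at an unadjusted p under 0.05), while fry, which asks whether a list's genes move on balance one way, called 6. Fry did not call photosynthesis, heat shock, glucosinolate, cell cycle or stomatal lineage and epidermis markers (adjusted p from 0.053 to 0.2), and it called the Dof family and nitrogen assimilation, which camera did not (adjusted p = 0.0077 each). With normexp the calls of flavonoid and anthocyanin, procambium, xylem and phloem, heat shock, shoot meristem and leaf development and stomatal lineage and epidermis markers were lost (adjusted p = 0.079, 0.18, 0.12, 0.65 and 0.3), the last 2 with a mean of -0.06. With only probes well above background on all 8 arrays, root tissue markers (0.22) and stomatal lineage and epidermis markers (0.092) lost theirs. The count without 1 array was 868, 735 and 836 without MP-Dof5.8 line 3 replicates 1, 2 and 3, 949, 829 and 790 without MP-GUS line 1 replicates 1, 2 and 3, 997 without MP-GUS line 4, and 7840 without MP-Dof5.8 line 4. With normexp, where the background fit failed on 1 array, 15 genes were called over all lines, and of the calls over all lines of genes named by the rule, that of DOF5.8 alone was kept.

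Line 3 and line 1 are the pair of lines with replicate arrays, and their comparison asks how MP-Dof5.8 line 3 differed from MP-GUS line 1. All MP-Dof5.8 line 3 arrays lay on slide 1, so slide as a block sets them against the 1 MP-GUS line 1 array there. Calls lost with the block can thus reflect the loss of control arrays as well as a slide difference. MRD1 rose by 6.47 (SE 0.08, adjusted p = 7.14e-06) and DOF5.8 by 4.52 (SE 0.05, adjusted p = 3.85e-06). The uncharacterised genes AT3G09450, AT5G09940 and AT3G19550, not well above background in MP-GUS line 1, were at least 3.76-fold, 2.30-fold and 2.65-fold higher (adjusted p = 0.0123, 0.0112 and 0.0016). AT3G19550 was also higher in MP-GUS line 4 than in MP-GUS line 1, so its difference was not particular to MP-Dof5.8 line 3. AT3G09450 and AT5G09940 were not well above background on either line 4 array, and AT3G19550 differed by 0.59 between the lines 4 (adjusted p = 0.328). The genes steepest downwards were not well above background on any line 3 array: AT1G52070 was at least 32.7-fold lower (adjusted p = 0.00224), CEP2 20.8-fold, AT5G60530 18.3-fold, AT5G04120 15.6-fold and AGP30 13.9-fold (adjusted p up to 0.0104). MP fell by 0.19 (SE 0.04, adjusted p = 0.0249). AT3G09450, AT5G09940, AT5G04120 and MP lost their calls with slide as a block (adjusted p = 0.0935, 0.0659, 0.0595 and 0.111). With normexp background correction the fitted values of AT3G09450, AT5G09940 and AT3G19550 in line 3 against line 1 turned negative.

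Of the glucosinolate genes 15 of 20 were higher and 0 lower in line 3 (camera adjusted p = 3.1e-06, and adjusted p = 0.47 with an estimated correlation), and 0 were called with slide as a block, which nearly coincides with construct here. Their median was 0.62 in line 3, 0.59 with the block and 0.41 between the lines 4, where 19 of 20 were above 0. BCAT4 rose by 0.68 and MYB28, a regulator of aliphatic glucosinolates, by 1.4 (adjusted p = 0.00879 and 0.0122, and 0.0701 and 0.109 with the block). Of the flavonoid genes 12 of 15 were higher and 0 lower (camera adjusted p = 3.1e-06, and adjusted p = 0.47 with an estimated correlation), and 6 were higher with the block. Their median was 0.76 in line 3, 0.69 with the block and 0.39 between the lines 4. Of the heat shock genes all 5 were higher (camera adjusted p = 0.0042, and adjusted p = 0.47 with an estimated correlation) and 0 with the block, with medians of 0.97, 0.69 and 0.56. Of the vascular genes 4 were higher and 14 lower (camera adjusted p = 0.011, and adjusted p = 0.47 with an estimated correlation), and 0 and 2 with the block, with medians of -0.23, -0.26 and -0.18. Of the root tissue markers 0 were higher and 4 lower (camera adjusted p = 0.028, and adjusted p = 0.47 with an estimated correlation), and 0 and 0 with the block, with medians of -0.60, -0.54 and -1.05.

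The auxin response list was called here, downwards, with 5 higher and 12 lower of 30 (camera adjusted p = 0.032, and adjusted p = 0.51 with an estimated correlation), and 1 and 1 with slide as a block. Its median was -0.25 in line 3, -0.21 with the block and 0.10 between the lines 4, where 17 of the 30 were above 0. The shoot meristem list was not called, although 9 of its 22 genes were higher and 2 lower (camera adjusted p = 0.11), and 3 and 0 with the block. Cell cycle genes shifted upwards (9 higher and 0 lower of 18, camera adjusted p = 0.00012, and adjusted p = 0.47 with an estimated correlation), with 0 called with the block and medians of 0.21, 0.17 and 0.09. So did stomatal lineage and epidermis markers (4 and 0 of 13, camera adjusted p = 0.028, and adjusted p = 0.51 with an estimated correlation), with 0 called with the block and medians of 0.15, 0.11 and -0.03. Photosynthesis genes shifted downwards (0 and 6 of 30, camera adjusted p = 0.00018, and adjusted p = 0.51 with an estimated correlation), with 0 and 1 with the block and medians of -0.16, -0.05 and 0.11.

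In all, 7240 genes (35.4%) were called in line 3 against line 1, 3643 higher and 3597 lower, most of them small, with a median size of 0.40 and 850 at least 2-fold. Most of the count did not hold with slide as a block, where 584 were called (266 higher, 318 lower), 529 of them among the 7240. With the block only 1 MP-GUS line 1 array stands against line 3, so the fall in the count does not measure slide effects alone. The difference between MP-GUS line 1 arrays on the 2 slides had the sign of the line 3 difference for 71.4% of the 7240 genes. It correlated with the line 3 difference across genes, which are not independent replicates, with r = 0.47. Without MP-Dof5.8 line 3 replicates 1 and 2 in turn 3563 and 1945 genes were called, and without MP-GUS line 1 replicates 2 and 3 in turn 2724 and 3789.

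The arrays of both lines 4 give an independent pair of lines with 1 array each, whose spread was borrowed from the lines with 3 arrays. Both arrays lay on slide 2, so slide as a block leaves their differences unchanged and alters only the borrowed spread. Calls between the lines 4 that are lost with the block are therefore no sign of a slide difference. MRD1 and DOF5.8 were 6.29 and 4.87 higher there (adjusted p = 0.000194 and 5.86e-05). AT1G52070, CEP2 and AGP30 were not well above background in MP-Dof5.8 line 4 and were at least 28.4-fold, 17.9-fold and 22.7-fold lower than in MP-GUS line 4 (adjusted p from 0.0334 to 0.0372). STM rose by 0.90 (adjusted p = 0.0257). MRD1 and DOF5.8 stayed called with slide as a block (adjusted p = 0.00068 and 0.000499), and AT1G52070, CEP2, AGP30 and STM did not (adjusted p from 0.0556 to 0.0642). CUC1 and DFR stood at 0.76 and 0.98 (adjusted p = 0.064 and 0.201), and DRN, SUC2 and XCP2 at -1.62, -0.35 and -0.47 (adjusted p from 0.0837 to 0.199). In all 186 genes were called, 85 higher and 101 lower (3125 at an unadjusted p under 0.05), and 24 with slide as a block. Without 1 array of line 3 or line 1 the count lay between 24 (without MP-GUS line 1 replicate 1) and 65 (without MP-GUS line 1 replicate 2), with 49, 38 and 46 without MP-Dof5.8 line 3 replicates 1, 2 and 3 and 32 without MP-GUS line 1 replicate 3.

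The pairs of lines share no array, so their direction can be compared gene by gene. BHLH100, an iron-deficiency regulator, stood at 2.69 and -2.67 in the pairs, and MRD1 at 6.47 and 6.29. Of the 7240 genes called in line 3 against line 1, 5679 (78.4%, 95% exact binomial interval 77.5 to 79.4, counting error only) had the same sign between the lines 4, with a median of 0.15 in that direction against 0.40 in line 3. Of the 850 that changed at least 2-fold, 678 (79.8%) did, with 0.58 against 1.44. Across all genes the log2 differences of the pairs correlated with r = 0.56. Called in both pairs were 70 higher and 87 lower genes, where independent lists of these lengths would share 15.1 and 17.7. Both comparisons use the spread of the lines with 3 arrays, so their lists are not independent and these numbers are no measure of chance. With slide as a block 95% of the genes then called had the same sign. The share was 75.5 to 89.6% without an MP-Dof5.8 line 3 array and 74.8 to 88.8% without an MP-GUS line 1 array.

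**Figure D3:**
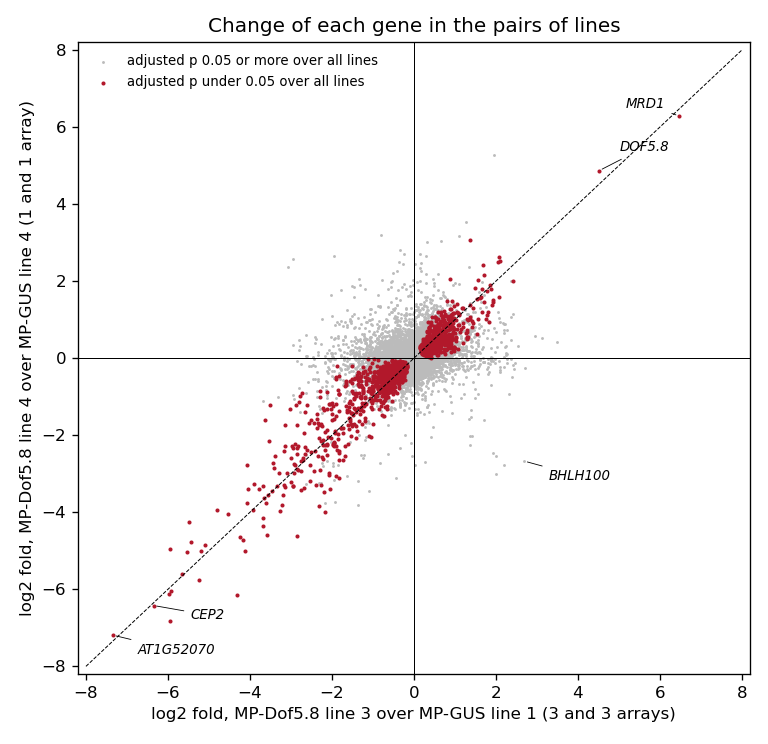
Fitted log2 difference of each of 20480 genes in MP-Dof5.8 line 3 against MP-GUS line 1 (horizontal axis, 3 and 3 arrays) and in MP-Dof5.8 line 4 against MP-GUS line 4 (vertical axis, 1 and 1 array); red points had an adjusted p under 0.05 over all lines and the dashed line marks equal values. MRD1 lay at 6.47 and 6.29, DOF5.8 at 4.52 and 4.87, and BHLH100 at 2.69 and -2.67.

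A test of the difference between the pairs of lines asks which genes respond unequally. The iron-deficiency regulator BHLH100 (AT2G41240) was 2.69 higher in line 3 than in line 1 and -2.67 between the lines 4, a difference of 5.36 (SE 0.24, adjusted p = 0.0156). The invertase and pectin methylesterase inhibitor family gene AT2G47050 differed by 3.6 (1.36 and -2.24, adjusted p = 0.0156) and AT2G14247, of unknown function, by 3.39 (1.36 and -2.03, adjusted p = 0.0494). The chorismate mutase gene CM2 differed by -1.92 (0.07 and 1.99, adjusted p = 0.0156) and the RNA gene AT2G46192 by -1.25 (-0.09 and 1.16, adjusted p = 0.0494). AT5G65440, named after its value was seen, differed by 2.68 (-0.44 and -3.12, adjusted p = 0.0367). These were the 6 genes called, 4 higher and 2 lower, with 2644 at an unadjusted p under 0.05 by limma. With slide as a block 0 were called (adjusted p from 0.183 to 0.299 for the 5 genes named by the rule), and without 1 array of line 3 or line 1 the count was 2 (without MP-Dof5.8 line 3 replicate 1), 1 (without MP-GUS line 1 replicate 3) or 0 (without each of the others). The calls of AT2G14247 and AT2G46192 were lost without any of these 6 arrays (adjusted p up to 0.18 and 0.26), those of BHLH100 and CM2 without any but MP-Dof5.8 line 3 replicate 1 (up to 0.111 each), and that of AT2G47050 without any but MP-GUS line 1 replicate 3 (up to 0.111). With no filter on dim probes none of the 5 was called (adjusted p from 0.0686 to 0.148). AT2G47050 was not called with capped normexp (0.126), AT2G14247 not as the mean of probes (0.0593) or from the deposited values (0.0542). AT2G46192 was not called in either of these 2 (0.0593 and 0.0542), with quantile normalization (0.0656) or with the array median (0.0779).

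The MP:GUS lines carry the same construct, and their comparison shows how far these lines lie apart, with 1 array of line 4. In simulated data this comparison recovered 28.4% of changes of 0.5, so its count is no upper limit. Nor does it cover the MP:Dof5.8 lines. MP-Dof5.8 line 4 correlated with the line 3 arrays, which lay on the other slide, with r of 0.977, 0.979 and 0.988. MP-GUS line 4 correlated with those of line 1 with r of 0.99, 0.992 and 0.988. CM2 was -1.98 (SE 0.07, adjusted p = 0.00366) and AT2G46192 -1.26 (adjusted p = 0.0202) in MP-GUS line 4 relative to line 1, which places the unequal response of both genes in that 1 array. The chloroplast RNA polymerase gene ATCG00170 fell by 1.07 (adjusted p = 0.0468) and AT2G47050 rose by 2.23 (adjusted p = 0.0334). AT3G19550, not well above background in line 1, was at least 2.52-fold higher (adjusted p = 0.0453). AT5G24990, not well above background in MP-GUS line 4 and named after its value was seen, was at least 1.73-fold lower (adjusted p = 0.0468). In all 6 genes were called, 2 higher and 4 lower, with 3646 at an unadjusted p under 0.05 by limma, and 0 with slide as a block (adjusted p from 0.055 to 0.173 for the 5 genes named by the rule). Without MP-Dof5.8 line 3 replicates 1, 2 and 3 in turn the count was 2, 1 and 1, and without any 1 of the MP-GUS line 1 arrays 0. The call of CM2 was lost without any 1 of those (adjusted p up to 0.071). The calls of AT2G46192, AT2G47050 and AT3G19550 were lost without any 1 of the arrays of line 3 or line 1 (up to 0.133 each), and so was that of ATCG00170 (up to 0.238). With normexp background correction, AT3G19550 (control lines) and AT2G47050 (control lines) read -0.72 and -0.41, and with capped normexp both lost their calls (adjusted p = 0.128 and 0.0738). With no filter on dim probes AT2G46192, AT2G47050, AT3G19550 and ATCG00170 were not called (adjusted p from 0.122 to 0.14). AT3G19550 and ATCG00170 were also not called with quantile normalization (0.0906 each), nor ATCG00170 with the array median (0.0521).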

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

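The slide and covariation tests of the root markers and the test of the neighbours of MRD1 were chosen only after the results were seen.

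A test of the difference between the pairs of lines singled out 6 genes whose response in line 3 was not that between the lines 4. They were BHLH100 (5.36), AT2G47050 (3.6), AT2G14247 (3.39), AT5G65440 (2.68), CM2 (-1.92) and AT2G46192 (-1.25), all on the log2 scale. BHLH100, a regulator of iron deficiency responses, stood at 0.90, 0.49 and 0.51 in MP-Dof5.8 line 3, at -4.23 in MP-Dof5.8 line 4, from -2.10 to -2.01 in MP-GUS line 1 and at -1.57 in MP-GUS line 4. CM2 and AT2G46192 stood lower in MP-GUS line 4 (-2.10 and -2.34) than in the other MP:GUS line. AT2G47050 was 2.23 higher in MP-GUS line 4 than in MP-GUS line 1, and -2.24 between the lines 4. Its difference between the lines 4 thus lies in the MP-GUS line 4 array, which its difference in line 3 against line 1 does not use. All 6 differences rest on 1 array of each line 4, and with slide as a block limma called 0.

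Signal also appeared in probes that carry no gene locus: 37 of the 2421 tested changed over all lines, 15 higher and 22 lower. The steepest, A_84_P796276, stood at 0.64 ± 0.05 (SD, n = 4) in MP:GUS and was not well above background on any MP:Dof5.8 array, at least 217-fold lower (adjusted p = 1.54e-08).

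The counts of called genes were set against other splits of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, 2 called at least as many genes as the real one (1726), itself included, so chance is not excluded by this count. The other one was the split by slide, with 4840, which points to a structure of the samples. It differs from the real split only by exchanging MP-Dof5.8 line 4 and MP-GUS line 1 replicate 1. Every remaining split called 0 genes. With slide as a block 1074 genes were called over all lines. The 10 splits of the 6 arrays of lines 3 and 1 are too few for a share under 0.05 (1 as large, the real one with 7240, and 0 in the highest other). A slide difference stays open for the line 3 count: 78.4% of its genes had the same sign between the lines 4. Pairs of arrays of the same construct on the same slide, up to 80% in whichever direction was more frequent, give no usable value for no change, since they include arrays of the comparison itself.

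The root markers were lower in MP:Dof5.8 samples. A slide difference as the whole cause is argued against by the 4 markers called over all lines, all 4 of which were called with slide as a block. This is limited, since the 4 were picked for their calls on the same arrays. They were not called in line 3 against line 1 with the block. EXPA7, EXPA18 and PRP3 among them were not well above background on any MP:Dof5.8 array. More root tissue in the MP:GUS samples stays open: the mean pairwise correlation of the markers over the 4 MP:GUS arrays was 0.14, at the 91.8th percentile of 10000 random lists of matched level (95th percentile 0.18). The endodermis genes CASP1, CASP2 and MYB36 (-0.41, -0.16 and 0.15) did not pass the test. A lower expression of root genes through DOF5.8 may be an alternative, and these data do not separate it from dissection. Whether the amount of root tissue also bears on the genes steepest downwards was not tested.

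MRD1 was high in MP:Dof5.8 samples of both lines. A difference between the seed stocks at that locus, confounded with the construct, stays open. Of the 2 measured genes next to MRD1, 1 was called: HEI10, a gene of meiotic crossover, rose by 0.85 (SE 0.07, adjusted p = 0.000558), and MSL4 stood at -0.28 (adjusted p = 0.11).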

How the results depend on the processing

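The fits within each slide and capped normexp were chosen only after the data were seen. Over the named genes, 2125 values were compared with the reported ones: 1792 kept direction and side of the threshold, 273 kept direction and lost the call, 44 gained one and 16 turned. DOF5.8 was 4.03 with normexp, 4.37 with capped normexp 4.58 to 4.61 with the other settings, and 4.54 to 4.65 without 1 array. Scan and slide coincide, so scan date was not run apart, and agreement has no value under normexp, where line 3 had 0 calls. Label numbers do not pair the samples (correlations of deviations 0.13, 0 and 0.05); as a block they gave 3640 genes over all lines, 6001 in line 3 and 7 lists, without shoot meristem and leaf development (adjusted p = 0.066) and stomatal lineage and epidermis markers (0.065). Dim signal limits the sizes of genes not well above background in a group, of which only bounds are known.

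With normexp, counts were 15 over all lines (1 higher, 14 lower), 0 in line 3, 0 in line 4, 0 for the difference and 0 for the control lines, with 3 gene lists. The cause lies in MP-GUS line 1 replicate 2: its highest local background was 65273 against a median of 55, and the fitted background mean was -1065.8 (7.3 when capped). Under it these turned: photosynthesis (mean -0.03, above the median of all genes), SCPL32 -0.67, AT1G07175 -0.55, AT4G26950 -0.03, ESE2 -0.19, PCC1 -0.17, REM1 -0.71, LOG3 -0.04, CKX5 -0.02, CUC2 -0.11, CUC1 -0.38, in line 3 AT3G09450 -0.32, AT5G09940 -0.53 and AT3G19550 -0.63, and in the control lines AT3G19550 -0.72 and AT2G47050 -0.41. DOF3.4 turned to -0.11 with the mean of probes. Normexp moved the median of all genes to -0.12 over all lines and -0.16 in line 3. Of the other changes the cause was not tested. Capped normexp gave 10 for the difference and 45 for the control lines; quantile normalization 3 for the control lines; no filter 1039 over all lines, 4153 in line 3, 8 in line 4, 0 for the difference, 1 for the control lines and an agreement of 83.8%. The filter on all 8 arrays gave 22 and the trend 50 for the control lines, and the mean of probes 3 for the difference. Slide as a block gave 1074, 584, 24, 0 and 0 and an agreement of 95%; fits within slides 27 and 9. Pairs of lines as a block gave 5953, line means 3183, and a 2-fold threshold 349 over all lines and 850 in line 3. Camera with an estimated correlation called 0 lists. Without 1 array the counts ranged from 735 to 7840 over all lines, 1945 to 7240 in line 3, 24 to 65 in line 4, 0 to 2 for the difference and 0 to 6 for the control lines; agreement from 74.8 to 89.6%. Of 87 named calls, 61 held without any 1 array and 26 were lost without at least 1.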

Other observations

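Words of the array's gene descriptions were tested for their share among called genes, a test chosen after the data were seen, over 846 words and directions with at least 20 genes each (Fisher's exact test, Benjamini-Hochberg). The test treats genes as independent, and a gene can carry several of the words. Among lower genes, peroxidases stood out with 18 of 69 (3.18 expected, adjusted p = 6e-07). The peroxidases AT4G26010, AT1G30870 and AT1G05250, not well above background on any MP:Dof5.8 array, were at least 9.6-fold, 8.64-fold and 4.31-fold lower (adjusted p = 0.00045, 0.00148 and 0.000356). Among other words, descriptions with inhibitor (23 of 127, adjusted p = 3.5e-06), storage (12 of 42, 4.5e-05), seed (13 of 51, 5.1e-05), harpin (9 of 28, 0.00034), pectinesterase (9 of 37, 0.0027) and extensin (9 of 42, 0.0062) also had lower genes. These words overlap: AT4G12510 and AT4G22666 counted for inhibitor, storage and seed alike. Of the 4 measured seed storage markers, 0 were lower. Genes described as allergens were lower in 11 of 27 cases (adjusted p = 3.5e-06), among them AGP30, AT5G57625 and MOP10, at least 15.7-fold, 9.55-fold and 8.71-fold lower. The root tissue markers also moved downwards, with a median of -0.71 (camera adjusted p = 0.0023, and adjusted p = 0.42 with an estimated correlation).

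Among higher genes, descriptions with auxin stood out with 22 of 123 (4.7 expected, adjusted p = 6e-07). They include SAUR20, AT5G18030, AT1G48660 and AT1G11803, which rose by 0.99, 1.09, 1.22 and 1.03 on the log2 scale (adjusted p from 0.000556 to 0.00683). The auxin response list did not share this direction, with 4 higher and 6 lower of 30 measured genes and a median of -0.23. Among other words, ribosomal descriptions had 30 of 369 higher (14.1 expected, adjusted p = 0.0058) and chaperonins 5 of 21 (adjusted p = 0.039).

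The principal components of the 8 arrays held 55.5%, 14.1% and 10.4% of the variance. On the first, MP-Dof5.8 line 3 stood at -56, -49.1 and -31.3, MP-GUS line 1 at 13.9, 34 and 40.1, MP-Dof5.8 line 4 at 5.7 and MP-GUS line 4 at 42.8.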
